A study of Homo sapiens with 32 samples.

How the data were processed

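Gene expression was measured on 32 GeneChip arrays in K-562, a human chronic myeloid leukemia cell line that grows in suspension and depends on the fusion kinase encoded at BCR. The arrays fall into 4 groups of 8: treatment-naive cells, cells made resistant to 0.5 µM imatinib, cells made resistant to 2 µM imatinib, and cells made resistant to 0.1 µM nilotinib. Per the labels, resistance was reached by raising the drug concentration step by step. RNA was isolated with a miRVana kit, and 100 ng was labelled for each array with the WT PLUS reagent kit. The growth text is the same for every sample and describes medium free of both drugs, so whether drug was present at harvest is not clear. Per the design text, each resistance has 2 biological replicates, called lines here, with 4 technical replicate arrays each. The naive arrays carry titles with the letters S and K, 4 arrays each. The labels do not say what the letters stand for, and each letter was counted as 1 naive set.

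The deposited values are summarised intensities per array feature on what reads as a log2 scale, from 1.24 to 14.2. The base of the logarithm was inferred from this range, since no label states it. The submitters' processing notes name Transcriptome Analysis Console 4.0, and the normalization method is not given in the sources used here. Array medians lay between 5.85 and 6.11, so the arrays had been brought to a similar but not identical level. No detection calls or background values were used, and the number of arrays limits the precision.

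Of 53617 features per array, 16098 carried 1 gene symbol and 37519 were unnamed here and entered only 1 alternative. A gene with more than 1 feature (779 genes) was represented by the feature with the highest mean over the arrays, which left 14884 genes. Symbols were matched by gene identifier to the annotation of GRCh38.p14, which served only for names and for the order of neighbouring genes.

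The 4 arrays of each set were averaged, and limma 3.58.1 in R 4.3.3 was fitted to the 8 set means with 1 mean per group, which leaves 4 residual degrees of freedom. There were 7 comparisons: each resistance against naive, all 6 resistant lines against naive, and the resistances against each other. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. For the 4 comparisons of sets within a group (line 1 against line 2 of each resistance and naive S against naive K), limma was fitted to the 32 arrays with 24 residual degrees of freedom, so these tests measure a difference against technical spread only. Errors given as ± are standard errors from limma, and confidence intervals are at 95%. In the fit to set means they pool the spread within all 4 groups, including groups outside the comparison. Named genes followed a rule. In comparisons with naive cells these were the 8 largest rises and 8 largest falls past the threshold with every line outside the range of the naive sets, filled with genes at an unadjusted p under 0.05 where fewer passed. The rule added, for each gene list, the passing member with the smallest adjusted p. It took 5 genes in each direction between resistances and 3 between sets of a group. BCR is given in each comparison with naive cells. Another 3 genes meant to be given in the same way are not analysed here, and 1 gene that the rule names in 2 comparisons (low imatinib against naive, and nilotinib against low imatinib) is left out.

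Gene lists (30 were fixed, and 29 had at least 5 measured members) were tested with camera in limma, with a preset correlation of 0.01 between genes and again with a correlation estimated from the data. They cover targets of the 2 drugs, alternative kinases, drug metabolism, MAPK output genes, STAT5 targets, the BCL2 family, cell adhesion, extracellular matrix, erythroid, megakaryocytic, granulocyte and monocyte, lymphoid, mast cell and basophil, epithelial and fibroblast, and stem cell genes. The others cover the cell cycle, interferon response, antigen presentation, integrated stress response, endoplasmic reticulum stress, hypoxia and glycolysis, cholesterol synthesis, autophagy and lysosome, antioxidant response, mesenchymal transition, Wnt and hedgehog signalling, cancer-testis antigens, targets of the DNA damage response, and ribosomal proteins. A list of drug transporters had 0 measured members and is not analysed here. Numbers of members in the results are those measured, which can be a small part of a list. Measured were 5 of 24 drug metabolism, 7 of 29 antigen presentation, 8 of 30 cancer-testis, 15 of 37 matrix, 20 of 48 erythroid and 5 of 9 drug target genes. Coverage was higher for others, such as 17 of 25 cholesterol synthesis and 36 of 45 cell cycle genes. The submitters may have reported cell adhesion and matrix themes from these arrays, so those lists may not be independent evidence.

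Alternatives left out the dimmest 40% of genes, used every array feature, applied quantile normalization or a shift to equal medians, fitted a mean-variance trend with robust moderation, or required a change of at least 2-fold. Others fitted the 32 arrays with the set as a random block, counted arrays as independent, counted 8 naive arrays as replicates, fitted only the groups compared, used the replicate number as a block, or left out each set in turn. The groups, comparisons, tests, threshold, rule for named genes, gene lists and these alternatives were chosen before the data were examined. After the data had been seen, the main direction of variation between technical replicate arrays was estimated from deviations from set means. It is called the technical axis and holds 16.8% of that variation, and it was taken out of every array as a further alternative. Leaving out array 4 of low-imatinib line 1 and pairing the lines crosswise were also added then, as was a search for stretches of neighbouring genes that move together. For that search the median change of each resistant line against naive was taken over 25 neighbours among 7437 genes of above-median expression, and its limit was the largest value in 100 shuffled gene orders.

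The fits were tested on simulated data with 200 changed genes among 14884. The changed genes were drawn at random, with independent noise at the spread of each gene. In the data, genes with large changes could have large standard errors and not pass, such as AHR in low imatinib (-4.24 ± 1.23). That error pools the spread of all groups: AHR stood at 10.69 and 6.63 in the nilotinib lines, and at 6.03 and 5.41 in the low-imatinib lines. The shares recovered therefore do not tell how many large changes were missed in the data. A change of 1 on the log2 scale was recovered in 54.0% of changed genes for low imatinib against naive, in 56.0% for high imatinib, in 52.0% for nilotinib and in 76.0% for all resistant lines, and a change of 2 in 94.0%, 94.0%, 94.0% and 100% of them.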

Results

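Whole-transcript expression was compared in 8 sets of 4 arrays from K-562 cells: naive S and naive K, and lines 1 and 2 resistant to 0.5 µM imatinib (low-imatinib lines), to 2 µM imatinib (high-imatinib lines) and to 0.1 µM nilotinib (nilotinib lines). Arrays of the same set correlated at r between 0.952 and 0.991 across genes. The first principal component of the 14884 genes held 29.3% of the variance and the second 18.1%. By root mean square distance, naive S and naive K were each other's nearest sets (0.257). High-imatinib line 1 lay nearer to nilotinib line 2 (0.403) than to high-imatinib line 2 (0.534), and high-imatinib line 2 lay nearest to low-imatinib line 2 (0.288). The technical axis, the main direction of variation between arrays of the same RNA source, was not level across groups: mean scores were -20.8 and -25.1 in naive S and K, 6.09 and 5.69 in the low-imatinib lines, -2.13 and 2.73 in the high-imatinib lines, and 21.2 and 12.3 in the nilotinib lines. Across genes, which are not independent replicates, this axis correlated at r = 0.607 with the change of all resistant lines against naive.

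**Figure D1:**
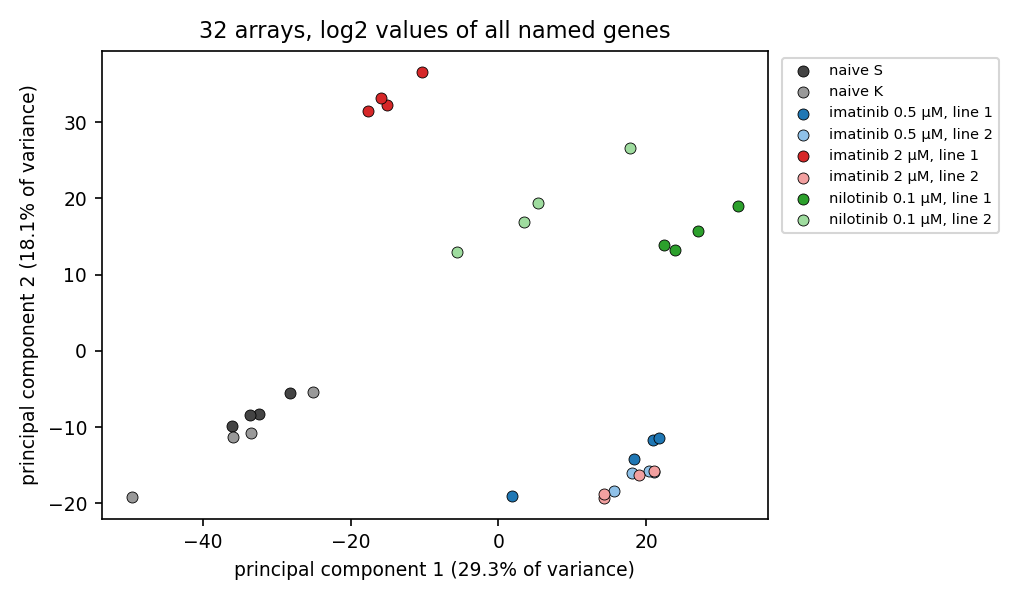
Scores of the 32 arrays on the first and second principal components of the log2 values of 14884 genes, which hold 29.3% and 18.1% of the variance, colored by set. The 4 arrays of each set carry the same color.

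**Figure D2:**
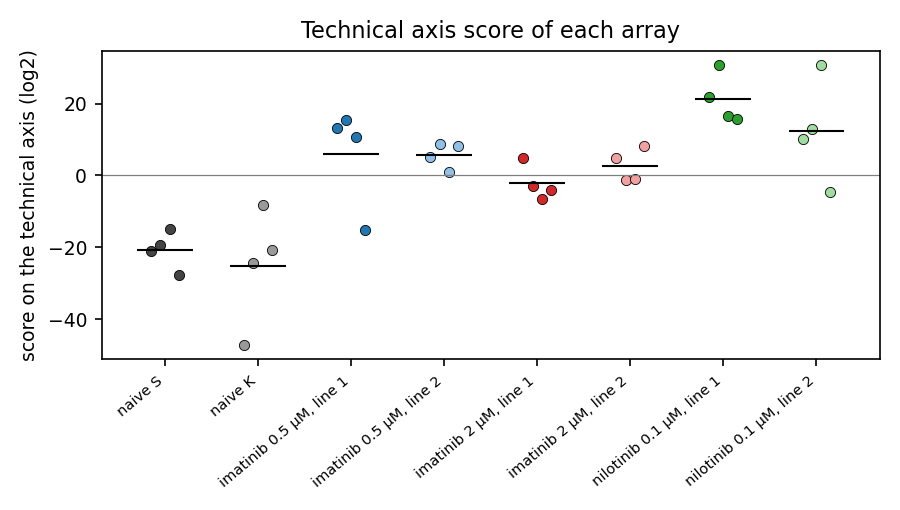
Score of each array on the technical axis (log2 units), grouped by set. Mean scores run from -25.1 in naive K to 21.2 in nilotinib line 1.

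All 6 resistant lines were compared with both naive sets to find expression shared by resistant cells whatever the drug. FN1, which encodes the matrix protein fibronectin, fell by 3.39 ± 0.25 on the log2 scale (10.5-fold, n = 6 lines against 2 naive sets, adjusted p = 0.0170). NMU, which encodes the neuropeptide neuromedin U, fell by 3.84 ± 0.56 (adjusted p = 0.0335), and ASS1, the argininosuccinate synthase of arginine synthesis, fell by 1.92 ± 0.23 (adjusted p = 0.0313). RELN, which encodes the secreted glycoprotein reelin, rose by 3.67 ± 0.41 (adjusted p = 0.0313). TXNIP, the thioredoxin-interacting arrestin that restrains glucose uptake, rose by 3.10 ± 0.51 (adjusted p = 0.0370), and its relative ARRDC4 by 2.77 ± 0.47 (adjusted p = 0.0375).

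Other large rises were those of ASXL3, a chromatin regulator (2.67 ± 0.51), SESN3, a stress-responsive sestrin (2.65 ± 0.45), CR1L, a complement receptor relative (2.47 ± 0.28), LTBP1, a matrix protein that binds latent growth factor (2.17 ± 0.44), and DAAM1, a formin that builds actin filaments (2.00 ± 0.38). HSPA1A and HSPA1B, which encode the inducible heat shock protein HSP70, fell by 2.19 ± 0.38 and fell by 2.26 ± 0.36; the pair are near-identical copies, and their features may not tell them apart. SAGE1, a cancer-testis gene, fell by 2.26 ± 0.36, PCED1B fell by 1.94 ± 0.20, and ZC3H12C, a zinc finger gene, fell by 1.59 ± 0.21. A second feature of TXNIP gave 1.28 ± 0.52. BCR itself stood at 0.29 ± 0.29 (95% interval -0.40 to 0.97, adjusted p = 0.506; 0.09 without nilotinib line 1), so it did not pass.

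By limma, 478 genes rose and 75 fell, 553 of 14884 at an adjusted p under 0.05, and 4432 had an unadjusted p under 0.05. All 6 lines lay above both naive sets in 17.0% of genes and below both in 15.9%. Chance gives 3.57% each if naive S and K vary as separately as the lines do. The labels do not say so, and S and K are each other's nearest sets. Chance may therefore give more, and no excess is read from these shares. The count was 0 without naive S, 0 without low-imatinib line 1, 0 without low-imatinib line 2, 2 without naive K (FN1 and PCED1B), 130 without nilotinib line 1, 923 without high-imatinib line 2 and 1742 without high-imatinib line 1. It was 12 with the technical axis taken out (3 higher, 9 lower). The median change of the 478 higher genes was then 0.48 in place of 0.82, and that of the 75 lower genes -0.61 in place of -0.76.

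**Figure D3:**
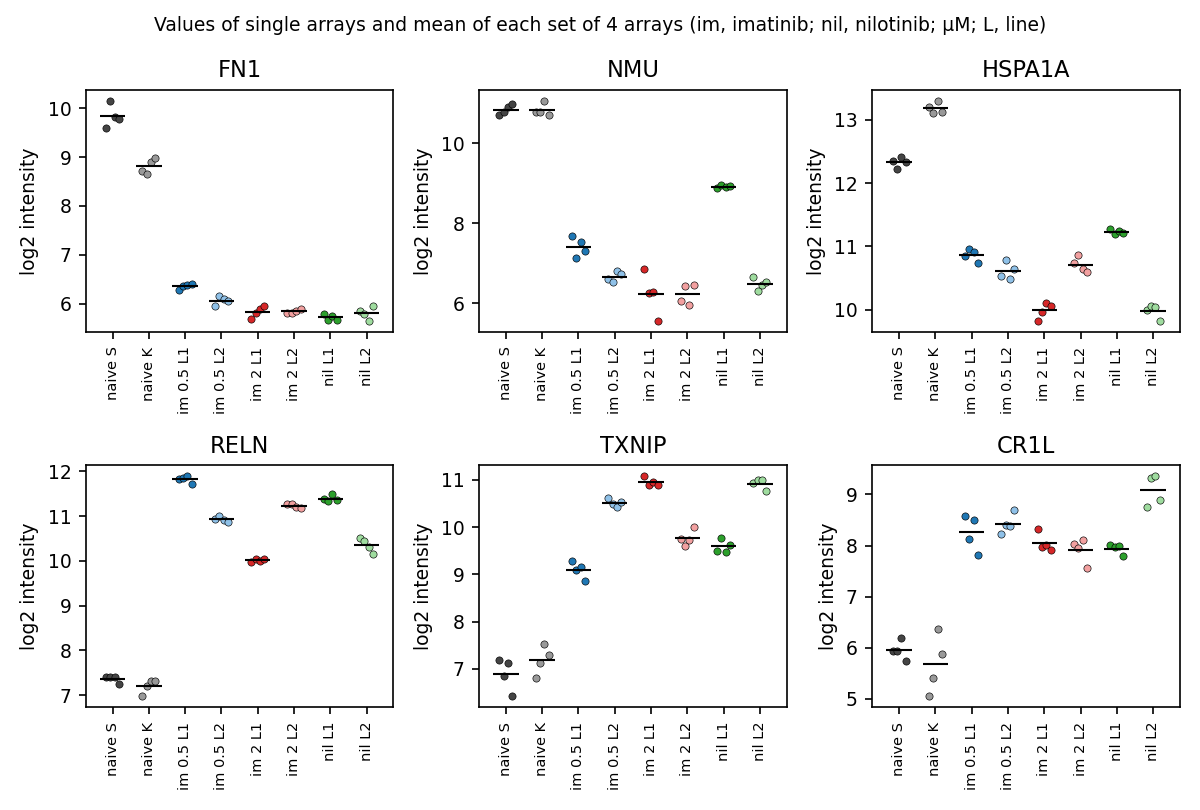
Log2 intensity of FN1, NMU, HSPA1A, RELN, TXNIP and CR1L on each array (points) with the mean of each set of 4 arrays (lines). Against the naive mean, FN1 and NMU stood at -3.39 and -3.84 and RELN at 3.67 over the 6 resistant lines.

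Genes of the cell cycle had a median change of 0.69 over 36 members (camera adjusted p = 6.59e-11, adjusted p = 0.459 with an estimated correlation). Of these, 6 passed the threshold over all genes, all higher, and 25 passed when adjusted over the list alone. KIF20A, a kinesin of cell division, rose by 0.95 ± 0.13, the mitotic kinase AURKA by 0.81 ± 0.12, the replication helicase subunit MCM5 by 1.22 ± 0.21 and the proliferation marker MKI67 by 1.05 ± 0.17. All 6 lines lay above both naive sets in 58.3% of members. These genes moved with the technical axis: with it taken out, their median was 0.30 (camera adjusted p = 1.68e-07).

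Cholesterol synthesis genes were higher (median 0.51 over 17 members, camera adjusted p = 5.58e-04, adjusted p = 0.459 with an estimated correlation). INSIG1, a feedback sensor of sterol levels, rose by 1.08 ± 0.15, SREBF2, the main transcription factor of the pathway, by 0.76 ± 0.15, and IDI1, an isoprenoid enzyme, by 0.68 ± 0.12; these 3 passed over all genes and 9 when adjusted over the list alone. Erythroid genes had a higher median too (0.66 over 20 measured members of 48, camera adjusted p = 0.00735, adjusted p = 0.660 with an estimated correlation). Of these, TAL1, a transcription factor of the erythroid lineage, rose by 1.12 ± 0.19 and UROD, a heme synthesis enzyme, by 0.92 ± 0.18, the 2 that passed both over all genes and adjusted over the list alone. The erythroid median was -0.08 in high-imatinib line 1, and all 6 lines lay above both naive sets in 20% of members, against 17.0% of all genes. Without the technical axis, the medians were 0.43 for cholesterol synthesis (camera adjusted p = 0.00122) and 0.42 for erythroid genes (camera adjusted p = 0.0125).

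Targets of the integrated stress response, which is driven by the transcription factor ATF4, had a lower median (-0.43 over 20 members, camera adjusted p = 0.00182, adjusted p = 0.459 with an estimated correlation). ATF5, a transcription factor of the pathway, fell by 0.94 ± 0.14 and STC2, a secreted glycoprotein, fell by 0.93 ± 0.17, the 2 that passed over all genes and adjusted over the list alone. The list median was 0.05 in high-imatinib line 1 and between -0.90 and -0.27 in the other lines. All 6 lines lay below both naive sets in 20% of members, against 15.9% of all genes. Over all lines the median was -0.59 with the technical axis taken out (camera adjusted p = 3.46e-08). Autophagy and lysosome genes were higher (median 0.34 over 24 members, camera adjusted p = 0.00735, adjusted p = 0.459 with an estimated correlation); ATG16L1, part of the autophagosome machinery, rose by 0.90 ± 0.15 as the 1 member that passed over all genes, and 8 passed when adjusted over the list alone. Lymphoid genes, markers of other blood cells, were lower by a small amount (median -0.23 over 16 members, camera adjusted p = 0.00182, adjusted p = 0.459 with an estimated correlation), with 0 members past either threshold in limma. With the technical axis taken out, the autophagy median was 0.14 (camera adjusted p = 0.199) and the lymphoid median -0.05 (camera adjusted p = 0.551), so neither kept its call.

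**Figure D4:**
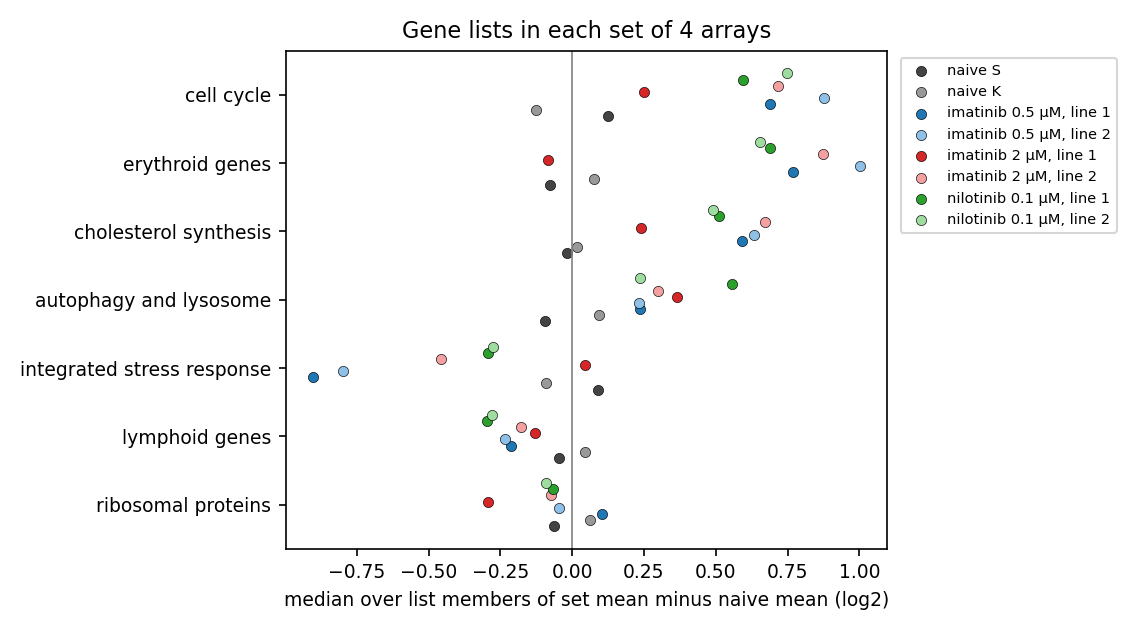
Median over list members of each set mean minus the naive mean (log2), for 7 gene lists in 8 sets of 4 arrays. The cell cycle median lay between 0.25 and 0.88 in the 6 resistant lines, and the erythroid median was -0.08 in high-imatinib line 1 and between 0.65 and 1.00 in the other lines.

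The other 23 lists did not pass in camera (adjusted p from 0.0520 to 0.996). Single members passed within them: CD58, an adhesion ligand, rose by 0.99 ± 0.15, GFI1B, a repressor of the megakaryocytic and erythroid lineages, by 1.04 ± 0.14, BAX, an executor of apoptosis, by 0.65 ± 0.13, and SESN1, a sestrin, by 1.16 ± 0.22. Cell adhesion had a median of 0.02 over 35 members, with 2 passing when adjusted over the list alone (CD58 and ICAM2), and extracellular matrix a median of -0.10 over 15, with 1 passing (FN1). The adhesion and matrix lists may not be independent evidence, since the submitters may have reported these themes from the same arrays. For cell adhesion the camera direction was downward although median and mean were above 0. Megakaryocytic genes had a median of 0.16 over 17 members. In that list GFI1B, GP6 (1.36 ± 0.36) and THBS1 (1.39 ± 0.42) were higher, and GP5 (-0.41 ± 0.10) and PF4 (-0.53 ± 0.13) lower, when adjusted over the list alone; GP5 and GP6 are platelet glycoproteins, and PF4 and THBS1 are granule proteins. List members named beyond the rule, in each comparison, were chosen after their values were seen. Targets of the DNA damage response had a median of 0.26 over 8 (BAX, SESN1 and AEN passed when adjusted over the list alone), the BCL2 family 0.05 over 15 (BAX passed), mesenchymal transition -0.04 over 12 (FN1, ZEB1 and ZEB2 passed, the latter pair higher), and drug metabolism -0.19 over 5 (GSTM1 passed, at -0.41 ± 0.11).

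No member passed in the remaining lists, either over all genes or adjusted over the list alone by limma. Drug targets had a median of 0.04 over 5 members, where the receptor kinase KIT stood at -2.27 ± 1.04 (adjusted p = 0.192), and STAT5 targets -0.12 over 16, where the kinase PIM1 stood at -2.37 ± 0.68 (adjusted p = 0.0852). Alternative kinases had a median of 0.12 over 20, MAPK output genes 0.01 over 16, hypoxia and glycolysis 0.22 over 18, and the antioxidant response 0.05 over 10. Granulocyte and monocyte genes stood at -0.12 over 19, mast cell and basophil genes at -0.24 over 7, epithelial and fibroblast genes at -0.26 over 10, and stem cell genes at -0.17 over 16. The interferon response had -0.07 over 33, antigen presentation -0.15 over 7, endoplasmic reticulum stress -0.26 over 8, Wnt and hedgehog signalling -0.06 over 20, cancer-testis antigens -0.13 over 8, and ribosomal proteins -0.07 over 27. Among these, 3 lists came to pass with the technical axis taken out: ribosomal proteins (median -0.24, camera adjusted p = 5.71e-06), endoplasmic reticulum stress (-0.44, adjusted p = 0.00251) and antigen presentation (-0.25, adjusted p = 0.0479). Median, mean or camera direction differed in sign for drug targets, alternative kinases, MAPK output, interferon response and Wnt and hedgehog signalling, all with a camera adjusted p of at least 0.622.

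Nilotinib resistance was compared with naive cells to find expression of the nilotinib lines. FN1 fell by 3.56 ± 0.31 (n = 2 lines against 2 naive sets, adjusted p = 0.0460), and AFP, which encodes alpha-fetoprotein, fell by 1.57 ± 0.14 (adjusted p = 0.0460). RELN rose by 3.59 ± 0.51 (adjusted p = 0.0485), CR1L by 2.70 ± 0.34 (adjusted p = 0.0460) and the sterol sensor INSIG1 by 1.43 ± 0.18 (adjusted p = 0.0460). CCP110 and CEP152, both of which encode centriole proteins, rose by 1.46 ± 0.18 and 1.42 ± 0.13. The zinc finger genes ZNF480 and ZNF75A rose by 1.86 ± 0.25 and 1.76 ± 0.16, and ATXN7L3B by 1.76 ± 0.17 (a second feature gave 0.93 ± 0.22).

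PCED1B fell by 1.85 ± 0.25 and its antisense neighbour PCED1B-AS1 fell by 1.52 ± 0.20. The cytokine receptor gene IL9R fell by 1.45 ± 0.20, NAV2, which guides neurite growth, fell by 1.44 ± 0.16 (other features -0.52 ± 0.17 and -0.86 ± 0.26), and ATF5 fell by 1.22 ± 0.18 (adjusted p = 0.0497). NMU stood at -3.13 ± 0.69 (-1.92 without line 2) and did not pass (adjusted p = 0.0616), nor did BCR at 0.39 ± 0.36 (adjusted p = 0.452). In limma 58 genes rose and 8 fell, and 4755 had an unadjusted p under 0.05. Both lines lay above both naive sets in 32.7% of genes and below in 34.7%. Chance gives 16.7% each only if naive S and K vary separately, and more if they do not. The count was 0 with quantile normalization, with the technical axis taken out, with every array feature, with only the groups compared in the fit and without naive S. It was 1 without naive K (FN1) and 6 without nilotinib line 1 (CR1L, NMU, CD36, CCDC68, LINC01203 and GS1-600G8.3, of which the last 4 were chosen after their values were seen), and all 66 lie close to the threshold, with 0.0460 the smallest adjusted p.

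In the nilotinib lines 6 lists passed in camera. Cell cycle genes were higher (median 0.69, adjusted p = 1.39e-09), with 0 members past the threshold over all genes and 21 adjusted over the list alone, among them KIF20A at 1.04 ± 0.16 and MCM5 at 1.26 ± 0.26. Cholesterol synthesis (median 0.49, adjusted p = 0.00232) had INSIG1 past the threshold over all genes and 6 members adjusted over the list alone, and autophagy and lysosome genes (median 0.42, adjusted p = 0.00380) had 7 adjusted over the list alone, such as ATG14 at 1.20 ± 0.28 (list medians 0.56 and 0.24 in lines 1 and 2). Erythroid genes had a median of 0.71 (adjusted p = 0.0122), lymphoid genes of -0.29 (adjusted p = 0.00232) and epithelial and fibroblast genes, markers of other cell types, of -0.38 (adjusted p = 0.0401), each with 0 members past either threshold in limma. With an estimated correlation all 6 missed the threshold (adjusted p = 0.650, and adjusted p = 0.70 for erythroid genes). Once the technical axis was taken out, medians were 0.32 for the cell cycle, 0.25 for cholesterol synthesis and 0.40 for erythroid genes, which stayed past the threshold, and 0.09 for autophagy and lysosome, -0.05 for lymphoid and -0.04 for epithelial and fibroblast genes, which did not. In that fit 3 further lists came to pass: the integrated stress response (median -0.50 in place of -0.24, camera adjusted p = 2.03e-05), ribosomal proteins (-0.26 in place of -0.05, adjusted p = 3.14e-05) and endoplasmic reticulum stress (-0.59 in place of -0.20, adjusted p = 0.00998).

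Low-dose imatinib resistance was compared with naive cells in the same way (n = 2 lines against 2 naive sets), and no single gene passed. The largest values were those of RELN (4.09 ± 0.51), ASXL3 (3.96 ± 0.63), NPY1R, a neuropeptide Y receptor (3.47 ± 1.15), and LTBP1 (3.17 ± 0.54), each higher in both lines than in both naive sets. TXNIP (2.77 ± 0.62, second feature 0.95 ± 0.64), SESN3 (2.75 ± 0.55), TF, which encodes transferrin (2.68 ± 0.93), and OSBPL6, an oxysterol-binding protein relative (2.64 ± 0.64), followed. Lower values included those of AHR, the aryl hydrocarbon receptor (-4.24 ± 1.23), CD24, a surface glycoprotein (-3.85 ± 1.20), NMU (-3.79 ± 0.69), STAP1, a signalling adaptor (-3.70 ± 1.5), FN1 (-3.12 ± 0.31), KIT (-3.10 ± 1.27) and CD53, a leukocyte tetraspanin (-2.87 ± 1.0). BCR stood at 0.34 ± 0.36 (adjusted p = 0.582).

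By limma on the set means 0 genes passed, the smallest adjusted p was 0.0574 (FN1, among others), and 3215 genes had an unadjusted p under 0.05. These errors pool the spread of all 4 groups, so disagreement between lines of the other resistances enters them. STAP1 had an SD of 0.10 in the low-imatinib lines and 0.18 in the naive sets, but stood at 9.58 and 4.42 in the high-imatinib lines. With only the low-imatinib and naive sets in the limma fit, which then rests on fewer sets, 1624 genes rose and 366 fell. In limma with the set as a random block over 32 arrays, 2256 genes rose and 416 fell. Both lines lay above both naive sets in 31% of genes and below in 31%. Chance gives 16.7% each only if naive S and K vary separately, and more if they do not.

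At list level 7 groups passed in camera for the low-imatinib lines. Cell cycle genes were higher (median 0.82, adjusted p = 7.71e-12, 20 of 36 adjusted over the list alone), as were cholesterol synthesis genes (median 0.63, adjusted p = 1.31e-04, 5 adjusted over the list alone: INSIG1, IDI1, FDPS, SREBF2 and MSMO1) and erythroid genes (median 0.83, adjusted p = 0.00291, 4 adjusted over the list alone: UROD, TAL1, BLVRB and PPOX). Integrated stress response targets were lower (median -0.85, adjusted p = 6.40e-07, 5 adjusted over the list alone), with the tryptophan tRNA synthetase WARS1 at -1.45 ± 0.21, the stress-induced inhibitor of growth signalling DDIT4 at -1.77 ± 0.40, the asparagine synthetase ASNS at -1.16 ± 0.30, ATF5 at -0.97 ± 0.18 and STC2 at -1.04 ± 0.21. Lower medians also held for lymphoid genes (-0.21, adjusted p = 0.00274, 0 adjusted over the list alone), antigen presentation (-0.41, adjusted p = 0.0268, 1 adjusted over the list alone, B2M at -0.75 ± 0.18) and granulocyte and monocyte genes (-0.16, adjusted p = 0.0470, 0 adjusted over the list alone). All 7 missed the threshold with an estimated correlation: adjusted p = 0.527 for erythroid genes, adjusted p = 0.437 for granulocyte and monocyte genes and adjusted p = 0.414 for the others. With the technical axis taken out, lymphoid and granulocyte and monocyte genes had medians of -0.05 and -0.09 and lost their calls, and the other lists kept theirs (cell cycle median 0.50, integrated stress response -0.96). Further lists that came to pass were MAPK output genes (-0.30, camera adjusted p = 0.0400), endoplasmic reticulum stress (-0.29, adjusted p = 0.0117), mesenchymal transition (-0.12, adjusted p = 0.0459) and ribosomal proteins (-0.17, adjusted p = 0.0127).

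High-dose imatinib resistance gave no passing gene either (n = 2 lines against 2 naive sets). RELN (3.34 ± 0.51), TXNIP (3.32 ± 0.62, second feature 1.21 ± 0.64), ARRDC4 (3.14 ± 0.58), AQP7P3, an aquaporin pseudogene with close copies (2.65 ± 0.97), and SESN3 (2.63 ± 0.55) had the largest values above naive. CD226, an activating immune receptor (2.58 ± 0.73), OSBPL6 (2.37 ± 0.64) and CR1L (2.17 ± 0.34) came next. NMU (-4.60 ± 0.69), FN1 (-3.49 ± 0.31), AHR (-3.47 ± 1.23), ICAM1, an adhesion molecule (-2.54 ± 0.57), SAGE1 (-2.52 ± 0.44), HSPA1B (-2.47 ± 0.44), HSPA1A (-2.40 ± 0.47) and PIM1 (-2.36 ± 0.84) had the largest values below naive. Without line 1 AQP7P3 stood at 1.29, and without line 2 OSBPL6 at 1.36. BCR stood at 0.14 ± 0.36 (adjusted p = 0.863).

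With limma on the set means 0 genes passed, the smallest adjusted p was 0.0718, and 2266 genes had an unadjusted p under 0.05. With the set as a random block, limma gave 1437 rises and 242 falls. Both lines lay above both naive sets in 24.3% of genes and below in 25.9%. Chance gives 16.7% each only if naive S and K vary separately, and more if they do not. Without high-imatinib line 1 the count on set means was 113, without line 2 it was 125, and without naive K it was 1 (FN1).

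In the high-imatinib lines 5 lists passed in camera. Cell cycle genes (median 0.53, adjusted p = 1.12e-08) had 8 members past the threshold adjusted over the list alone, such as MCM5 at 1.47 ± 0.26 and AURKA at 0.77 ± 0.15. Cholesterol synthesis genes (median 0.44, adjusted p = 0.00132) had 6, such as STARD4, a sterol carrier, at 1.18 ± 0.29. Autophagy and lysosome genes (0.37, adjusted p = 0.00348), ribosomal proteins (-0.19, adjusted p = 0.0135) and lymphoid genes (-0.16, adjusted p = 0.0140) each had 0 by limma adjusted over the list alone. In lines 1 and 2 the medians were -0.29 and -0.07 for ribosomal proteins, 0.25 and 0.72 for the cell cycle and 0.24 and 0.67 for cholesterol synthesis. All 5 missed the threshold with an estimated correlation (adjusted p = 0.577, and adjusted p = 0.692 for ribosomal proteins). With the technical axis taken out the medians were 0.30 for the cell cycle, 0.39 for cholesterol synthesis and -0.33 for ribosomal proteins, which kept their calls, and 0.17 for autophagy and lysosome and -0.03 for lymphoid genes, which lost them. Antigen presentation (-0.23, camera adjusted p = 0.0412), the integrated stress response (-0.23, adjusted p = 0.00211) and endoplasmic reticulum stress (-0.30, adjusted p = 0.00992) came to pass in that fit.

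The 2 imatinib doses were set against each other to find what differs with the level of resistance. WARS1 stood 1.55 ± 0.21 higher in the high-imatinib lines and DDIT4 1.59 ± 0.40 higher (95% interval 0.64 to 2.53), both targets of the integrated stress response, a list whose median was 0.39 (camera adjusted p = 3.29e-07, adjusted p = 0.605 with an estimated correlation). Against naive, medians of this list were 0.05 and -0.46 in high-imatinib lines 1 and 2, and -0.90 and -0.80 in the low-imatinib lines. The list was thus less reduced in the high-imatinib lines and not clearly above naive, and line 1 carried much of the difference. The leukocyte signalling genes LCP2 (2.42 ± 0.95, interval 0.16 to 4.67) and SYK (1.87 ± 0.68), the macrophage glycoprotein gene CD68 (2.12 ± 0.73) and TRIM38, a ubiquitin ligase gene (1.68 ± 0.53), were also higher. CARMIL1, a regulator of actin capping (-2.65 ± 0.57, interval -4.00 to -1.30), TFAP2B, a transcription factor (-2.29 ± 0.40, interval -3.24 to -1.34), FGF2, a fibroblast growth factor (-2.27 ± 0.79), ASXL3 (-2.11 ± 0.63) and PYCARD, an inflammasome adaptor (-1.99 ± 0.59), were lower. No gene passed in limma (0 genes, smallest adjusted p = 0.799, 722 genes at an unadjusted p under 0.05, 413 genes with the set as a random block). High-imatinib line 1 carried several of these values: without it LCP2 stood at 0.67, CD68 at 0.80, TRIM38 at 0.72, SYK at 1.10 and FGF2 at -1.42. Without that line the count was 2 (GALNT5 and LOC650226, chosen after their values were seen), and without line 2 it was 270.

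MAPK output genes also had a higher median at the high dose (0.38, camera adjusted p = 0.00661), as was antigen presentation (0.16, adjusted p = 0.0415), and ribosomal proteins (-0.15, adjusted p = 4.82e-04), cell cycle genes (-0.20, adjusted p = 6.98e-04) and erythroid genes (-0.33, adjusted p = 0.0313) were lower. High-imatinib line 1 alone carried part of this. Against naive, MAPK medians were 0.55 and -0.21 in high-imatinib lines 1 and 2 and -0.31 and -0.29 in the low-imatinib lines. Erythroid medians were -0.08 and 0.87 against 0.77 and 1.00. Cell cycle medians were 0.25 and 0.72 against 0.69 and 0.88, and ribosomal medians -0.29 and -0.07 against 0.10 and -0.05. Each list missed the threshold with an estimated correlation (adjusted p = 0.664), and erythroid genes also missed it with the technical axis taken out (median -0.28, camera adjusted p = 0.0502). Adjusted over the list alone, WARS1 was the 1 member of these lists to pass, and it was chosen after its value was seen.

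Nilotinib is built on the phenylaminopyrimidine scaffold of imatinib, with the amide reversed and the N-methylpiperazine part replaced by a methylimidazole and a trifluoromethyl group. The doses differ (0.1 µM nilotinib against 0.5 and 2 µM imatinib), so the drugs are set side by side and not at matched dose. FN1 stood at -3.56 ± 0.31 in the nilotinib lines, -3.12 ± 0.31 in the low-imatinib lines and -3.49 ± 0.31 in the high-imatinib lines against naive, and RELN at 3.59 ± 0.51, 4.09 ± 0.51 and 3.34 ± 0.51. Against the low-imatinib lines, the nilotinib lines were higher in LAPTM5, a lysosomal protein of blood cells (4.54 ± 1.74, 95% interval 0.42 to 8.65), IFITM2, an interferon-induced membrane protein (4.40 ± 1.45, 0.98 to 7.83), CD53 (2.95 ± 1.0, 0.56 to 5.33) and CD24 (2.94 ± 1.20). They were lower in NPY1R (-3.64 ± 1.15, -6.36 to -0.92), SGIP1, an endocytic adaptor (-2.47 ± 0.35, -3.31 to -1.63), LTBP1 (-1.92 ± 0.54), CARMIL1 (-1.88 ± 0.57) and DLK1, a Notch ligand relative (-1.86 ± 0.57). None of the genes named for this pair of resistances passed in limma.

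Antigen presentation genes were higher in the nilotinib lines than in the low-imatinib lines (median 0.56, camera adjusted p = 1.31e-06, adjusted p = 0.402 with an estimated correlation). Adjusted over the list alone, 4 of 7 measured members (the list holds 29) passed: B2M, the light chain of class I molecules (1.08 ± 0.18), the peptide loading factor TAPBP (1.18 ± 0.25) and the peptide trimming enzymes ERAP1 (0.56 ± 0.16) and ERAP2 (0.73 ± 0.15). Integrated stress response targets (0.56, adjusted p = 1.18e-04, adjusted p = 0.431 with an estimated correlation), MAPK output genes (0.38, adjusted p = 7.61e-04, adjusted p = 0.530 with an estimated correlation) and the interferon response (0.15, adjusted p = 0.0346, adjusted p = 0.431 with an estimated correlation) were higher. So were autophagy and lysosome genes (0.12, adjusted p = 0.0276), while Wnt and hedgehog genes were lower (-0.11, adjusted p = 0.0280), both at an adjusted p = 0.712 with an estimated correlation. In limma adjusted over the list alone, WARS1 (1.13 ± 0.21) of the stress response list and SAMD9 (1.80 ± 0.33), an interferon-induced gene, also passed. Nilotinib line 1 carried the interferon and autophagy differences, with medians against naive of 0.05 and 0.56, where line 2 had -0.09 and 0.24 and the low-imatinib lines -0.10 and -0.09, and 0.23 and 0.23. Integrated stress response medians against naive were -0.29 and -0.27 in the nilotinib lines and -0.90 and -0.80 in the low-imatinib lines, so this list was less reduced and not above naive. The autophagy median was 0.07 with the technical axis taken out (camera adjusted p = 0.164), which ended that call. No single gene passed over all genes in limma (0 genes, smallest adjusted p = 0.525, 1028 at an unadjusted p under 0.05, 550 with the set as a random block). Nilotinib line 1 carried much of CD24, CARMIL1 and DLK1, which stood at 1.19, -0.94 and -1.17 without it. The count was then 7, and without line 2 it was 28.

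Against the high-imatinib lines, the nilotinib lines were higher in DDX60L, a helicase of antiviral response (2.05 ± 0.26, 95% interval 1.43 to 2.67), ICAM1 (2.12 ± 0.57, 0.78 to 3.46), GALNT5, a glycosyltransferase (2.27 ± 0.68, 0.67 to 3.87), ZNF117 (1.90 ± 0.46) and ABHD3, a phospholipase (1.82 ± 0.50). They were lower in SGIP1 (-1.79 ± 0.35, -2.63 to -0.96), TSPAN5, a tetraspanin (-1.67 ± 0.59), and 3 members of a family of near-identical copies, USP17L12 (-1.10 ± 0.28), USP17L9P (-1.10 ± 0.28, another feature -0.15 ± 0.15) and USP17L15 (-1.0 ± 0.30), whose features cannot be assigned to 1 copy with certainty. Antigen presentation (median 0.37, camera adjusted p = 0.00184, adjusted p = 0.80 with an estimated correlation), cell cycle genes (0.19, adjusted p = 0.00369) and ribosomal proteins (0.12, adjusted p = 0.0449) were higher, the latter pair at an adjusted p = 0.933 with an estimated correlation and both losing the call with the technical axis taken out (medians 0.02 and 0.03). High-imatinib line 1 stood apart in both lists (0.25 and -0.29 against naive, with 0.72 and -0.07 in line 2). The interferon response came to pass with the axis taken out (median 0.09, camera adjusted p = 0.0101). By limma 0 genes passed (smallest adjusted p = 0.744, 943 at an unadjusted p under 0.05, 201 with the set as a random block). Without nilotinib line 1 ICAM1 stood at 1.12, without high-imatinib line 1 ABHD3 at 1.02, USP17L12 and USP17L9P at -0.72 and USP17L15 at -0.60, and without high-imatinib line 2 GALNT5 at 1.04 and TSPAN5 at -0.81. Leaving out a line gave 25 (high-imatinib line 1), 16 (high-imatinib line 2), 6 (nilotinib line 1) or 35 (nilotinib line 2), and a missed threshold does not show that the drugs act alike.

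The changes of the 3 resistances against naive were compared with each other to see how far they coincide. Across genes, the changes correlated at r = 0.746 (low and high imatinib), 0.733 (low imatinib and nilotinib) and 0.776 (high imatinib and nilotinib). Unchanged groups simulated against the same naive sets gave 0.499, 0.498 and 0.499, since all 3 share their controls. The simulation holds no technical difference between naive and resistant sets, although scores on the technical axis differ between them. Such a difference could raise the observed values too, so how much of the excess comes from resistance is open. The covariances were 0.131, 0.156 and 0.141 against a simulated 0.0306. With 1 resistance set against naive S and the other against naive K, r lay between 0.590 and 0.647, with a single set in each part of the controls and no value for unchanged groups. With the set as a random block, a fit that treats arrays in part as replicates, 984 genes passed in all 3 resistances (904 higher, 80 lower). On set means 0 did so. The counts for pairs that follow are from the same block fit. Pairs shared 982, 1652 and 1214 higher genes, where independent lists give 218, 440 and 280, and 131, 178 and 109 lower genes, where they give 6.76, 22.1 and 12.9. Independent lists leave out the shared controls, so part of the excess may come from these.

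The lines of a resistance were compared because the design text gives them as biological replicates. Low-imatinib line 1 exceeded line 2 in the cancer-testis genes GAGE13 (2.93 ± 0.10) and GAGE2A (2.38 ± 0.13), members of a family of near-identical copies, and in SNAI2, a transcription factor of mesenchymal transition (2.61 ± 0.11); it was lower in BCOR, a transcriptional corepressor (-3.46 ± 0.11), FAXDC2 (-2.48 ± 0.14) and the immediate early gene EGR1 (-2.30 ± 0.11). High-imatinib line 1 exceeded line 2 in LAPTM5 (6.24 ± 0.14), the phospholipid-binding annexin ANXA1 (6.22 ± 0.12) and NTS, which encodes neurotensin (5.92 ± 0.14), and was lower in NPY1R (-4.01 ± 0.19), the matrix proteoglycan gene VCAN (-3.71 ± 0.12) and CACHD1 (-3.68 ± 0.13). Nilotinib line 1 exceeded line 2 in SCG3, a secretory granule protein (6.34 ± 0.19), SNAI2 (5.18 ± 0.11) and PLN, which encodes phospholamban (4.73 ± 0.18), and was lower in NTS (-4.44 ± 0.14), the scavenger receptor CD36 (-4.21 ± 0.14) and MYO3B (-3.62 ± 0.09). All of these passed, with n = 4 technical arrays per line, at an adjusted p of at most 1.07e-14 in limma.

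Between lines, 2788 genes passed for low imatinib (1482 higher and 1306 lower in line 1), 4916 for high imatinib (1971 and 2945) and 4101 for nilotinib (2392 and 1709). At a change of at least 2-fold the counts were 158, 833 and 566. Naive S and naive K differed in 1840 genes (962 higher and 878 lower in S), and in 41 at 2-fold. This fit pools the spread of all 8 sets, and the naive arrays varied more than the others. The median gene SD between arrays was 0.186 and 0.193 in naive S and K and between 0.123 and 0.180 in the resistant lines. With limma fitted on the naive arrays alone, 219 genes passed. S was lower in JUN, an immediate early gene (-1.86 ± 0.12), CHORDC1, a partner of heat shock proteins (-1.58 ± 0.14), and SCARNA9L (-1.37 ± 0.21), and higher in RAET1K (1.27 ± 0.25), CRSP8P (1.14 ± 0.23) and KRTAP4-8 (1.09 ± 0.24). RAET1K, CRSP8P and KRTAP4-8 lay between 4.62 and 5.90 in the naive sets, below the naive array medians. The SD of CRSP8P between arrays was 0.50 in S and 0.61 in K, so its pooled error understates its spread here. The tests are against technical spread and carry no biological replication, and without array 2 of naive S the 1840 genes became 1126.

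Read along the order of genes on the reference assembly, each of the 6 resistant lines had stretches of neighbouring genes whose median change against naive lay beyond the limit from shuffled orders. There were 28 such runs, 13 of them higher, and 11 ran at over 2 times the shift of each other line. In low-imatinib line 1 the 55 genes from SNX17 to FOXN2 had a median of 0.78 (SD over genes 0.69), with 51 of them higher, and the 35 genes from NRIP1 to DSCR8 a median of 0.58. In low-imatinib line 2 the 26 genes from ELF4 to MTM1 had a median of -0.65. In high-imatinib line 1 the 70 genes from PRKCQ-AS1 to ALOX5 had a median of 0.65 with 64 higher, and in high-imatinib line 2 the 78 genes from RNF111 to IDH3A a median of 0.57. In nilotinib line 1 the 56 genes from USP18 to RGL4 had a median of -0.74 with 47 lower (of these, the 23 from THAP7-AS1 to RGL4 had -0.69, and -0.62 in nilotinib line 2), and in nilotinib line 2 all 82 genes from ZNF589 to CLDND1 were lower, with a median of -0.52 (SD 0.30). BCR lies between USP18 and RGL4, and its level in nilotinib line 1 was 8.85 against 7.84 in naive S and 7.90 in naive K. This search was added after the comparisons had been seen.

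**Figure D5:**
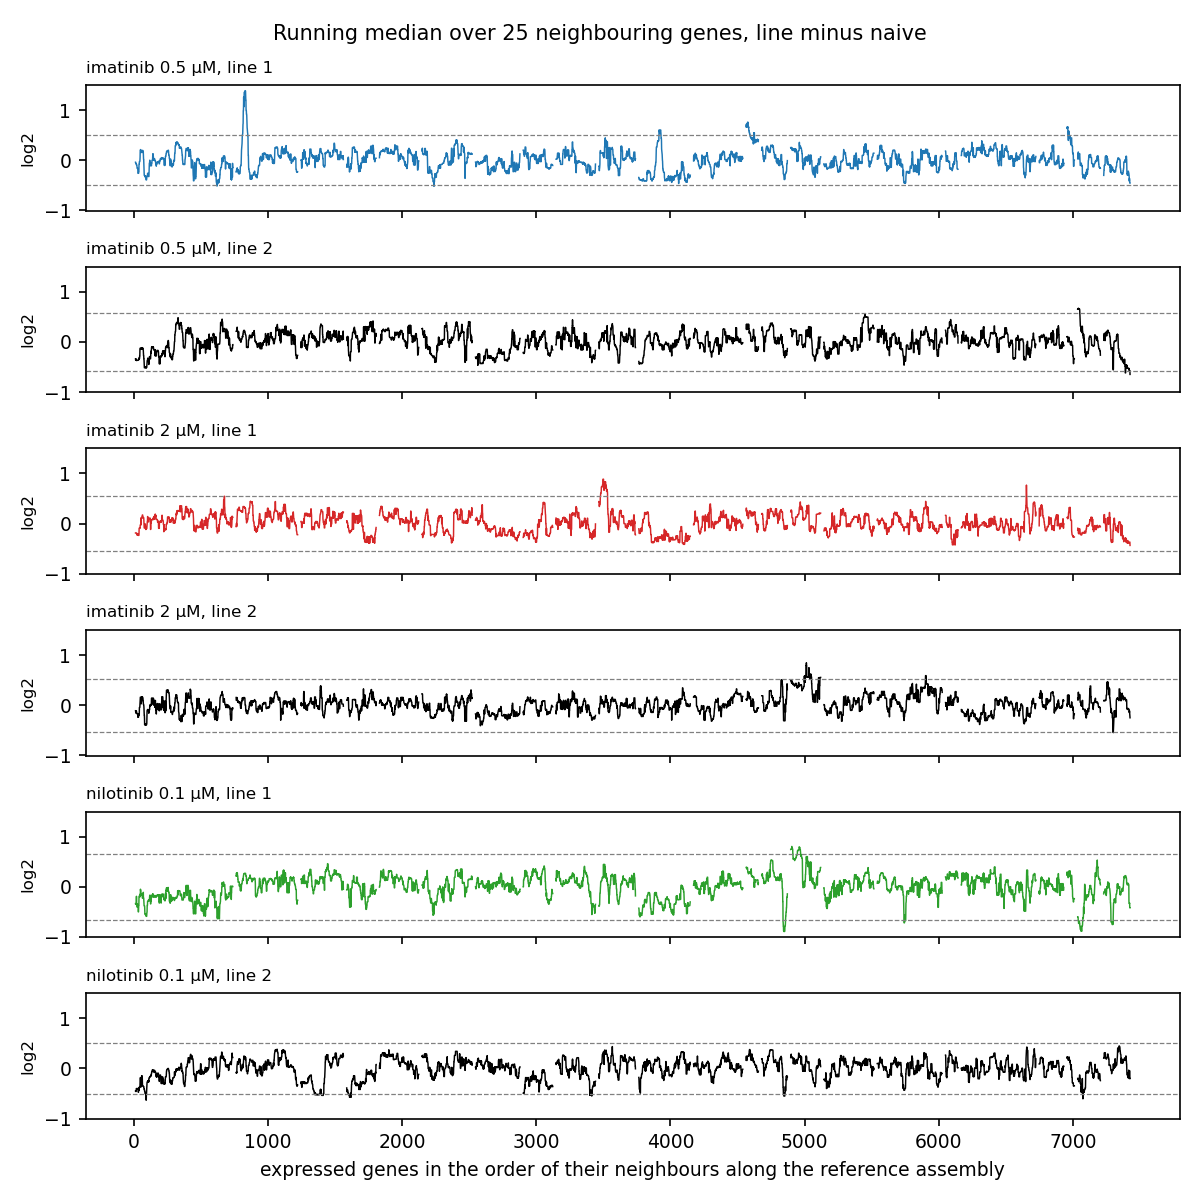
Running median over 25 neighbouring genes of line minus naive (log2) along the order of 7437 genes, for each of the 6 resistant lines, with dashed lines at the largest value of 100 shuffled orders. The largest running median was 1.39 in low-imatinib line 1, where the shuffled limit is 0.50, and 0.63 in nilotinib line 2, where it is 0.52.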

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

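Chosen only after the results had been seen were the tests of the technical axis and of quantile normalization on the genes called in all resistant lines, with their bounds, the distance tests, the search for shifted runs and its shuffled orders; the splits of samples and the further tests on the runs were fixed before their outcomes were known.

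Most genes called between resistant lines and naive sets were higher in the resistant lines (478 of 553), which did not hold with the technical axis taken out (3 higher and 9 lower). Brighter genes tended to have higher changes, with a Spearman r of 0.511 between change and mean expression across genes. With the dimmest 40% left out, the median change of all genes was 0.20, and 710 of 775 calls were higher (91.6%). The SD over features was 1.65 and 1.68 in naive S and K and between 1.73 and 1.78 in the resistant lines. The list tests made no adjustment for expression level, so whether list changes follow from this was not tested. The counts of calls that stayed, 10 with the technical axis taken out and 273 with quantile normalization, were looked at first, and the tests on medians were written after them. Among the 478 genes the median change went from 0.82 (SD over genes 0.33, median SE 0.135) to 0.48 (median SE 0.131) with the technical axis taken out, which is consistent with a technical difference between arrays as part of the change, although the axis may also carry a real difference between the cells, since its scores follow the groups. The 10 genes past the threshold in both fits were ATXN7L3B, NIN, ZNF75A, ASS1, FN1, NAV2, PCED1B, PCED1B-AS1, AFP and KCTD14, 7 of them lower and 3 higher. The axis as estimated did not account for all of their change, but they were picked by that result, so it is no separate test. The axis holds 16.8% of the variation between technical replicate arrays, and other technical differences are not covered. A difference between resistant and naive cells stays a hypothesis for these genes. Quantile normalization left a median of 0.73, a step of less than 2 median SE. That bound is the error of single genes and is wide for a median over 478 genes. Of the 478, 223 then passed, and 74.0% of all calls were higher in place of 86.4%. Unequal distributions of the arrays thus do not account for most of the median change, but as a part of it they stay open.

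For the same comparison, of 28 splits of the 8 sets into 6 and 2, the real split alone (1 split) reached its 894 genes. These counts are from the fit with only these groups. The highest other split, which set high-imatinib line 1 and nilotinib line 2 apart, gave 32. If naive S and K are separate cultures, this argues against chance. It does not exclude chance, since 1 of 28 is the smallest share that such splits can reach. The labels do not say whether S and K are separate, and they are each other's nearest sets, so on other footing the splits would not test this. The split that set apart low-imatinib line 2 and high-imatinib line 2, nearly as close (0.288 against 0.257), gave 3 genes. Its other group mixed both naive sets with resistant lines, so any difference between these widens the spread and lowers the count. That split therefore does not show what closeness alone would give.

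High-imatinib line 1 lay nearer to nilotinib line 2 than to the other high-imatinib line, by 0.131 in distance (SD over 200 resamplings of arrays 0.0171). With the technical axis taken out the gap was 0.148 (SD 0.0070), so the axis was not its cause. Exchanged labels of high-imatinib line 1 and nilotinib line 1 may also be considered. An exchange of high-imatinib line 2 and nilotinib line 2 would give the same pairing. The test, written for the first exchange, asked whether nilotinib line 1 lay nearest to high-imatinib line 2. The distance of nilotinib line 1 to high-imatinib line 2 exceeded that to its nearest set, low-imatinib line 1, by 0.0294 (SD 0.0160), within 2 SD. This cannot decide on an exchange, since lines of 1 resistance need not be nearest: high-imatinib line 2 lay nearest to low-imatinib line 2 (0.288). Whether the labels were exchanged stays open, and a difference between the lines themselves stays open as well, untested.

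Runs of neighbouring genes were shifted in each resistant line, and 11 of the 28 runs ran at over 2 times the shift of each other line, while others were shared between lines. The largest of 100 shuffled orders is the limit that defines a run, and the largest running median lay above it in all 6 lines (from 0.63 against 0.52 to 1.39 against 0.50), which argues against a chance order of genes but is no separate test of it. With the technical axis taken out 20 of the 28 runs, and 10 of these 11, kept 0.5 or more of their shift, so the axis does not account for most runs. In 3 of the 4 runs with at least 3 zinc finger genes, the other genes had at least 0.5 of the zinc finger median in the same direction. In 1 of them, from ZNF592 to TARS3, the zinc finger genes had moved little (0.12 against 0.55). In the run from USP18 to RGL4 the zinc finger median was 0.86 and that of the other genes -0.76. Sequence shared within zinc finger clusters was tested in these 4 runs alone, and in 3 of them it does not account for the shift of the other genes. A line-specific gain or loss of chromosome segments is a candidate explanation for 9 of the 10 runs particular to 1 line that kept their shift. No copy number was measured here. The run from USP18 to RGL4 in nilotinib line 1 is left out of this, since the 23 genes from THAP7-AS1 to RGL4 within it had a median of -0.62 in nilotinib line 2 and -0.69 in line 1.

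The lines of each resistance differed in 2788 genes (low imatinib), 4916 (high imatinib) and 4101 (nilotinib) when tested against technical spread. Among the 35 splits of the 8 arrays of a resistance into 4 and 4, fitted on those arrays alone, 1 split, the real one, gave as many genes in each case, with 2465 against 1 in the highest other for low imatinib, 5704 against 0 for high imatinib and 3992 against 0 for nilotinib. Naive S and K gave 219 against 1. These splits set a difference between single samples against technical spread, so they decide nothing on chance differences between lines, which stay open.

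Single arrays stood apart from the other 3 of their set in 6 of 32 searches. For 4 independent values chance gives about 1 in 20. All but that of low-imatinib line 1 were on correlations within the set, which share pairs of arrays and are not independent. The rate of 1 in 20 does not hold for these, so the 6 do not show an excess over chance. Array 2 of naive S had a median correlation of 0.955 with its set (others 0.977 to 0.980). Array 1 of naive K had 0.970 (others 0.980). Array 4 of low-imatinib line 1 scored -15.2 on the technical axis (others 10.8 to 15.5). In low-imatinib line 2 the correlation of array 2 was 0.986 (others 0.988), and in high-imatinib line 1 that of array 1 was 0.985 (others 0.988). Array 2 of nilotinib line 2 had the highest correlation of its set, 0.987 (others 0.982 to 0.983).

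Among features unnamed here, 9 passed between all resistant lines and naive (5 higher, 4 lower) in the fit of every array feature.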

How the results depend on the processing

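The tests with the technical axis taken out, without array 4 of low-imatinib line 1 and with crossed pairs were chosen after the data had been seen. In the order low imatinib, high imatinib, nilotinib and all resistant lines against naive, the reported counts are 0, 0, 66 and 553. They were 2672, 1679, 3696 and 3660 with the set as a random block, 6482, 4969, 8785 and 8199 (55.1% higher) with arrays as independent, and 2104, 1047, 3367 and 5130 (66.9% higher) with 8 naive arrays as replicates; these 3 treat arrays as replicates in whole or in part. A shift to equal medians gave 172, 0, 1615 and 1677 (95.5% higher), and put the median change of all genes at 0.14 for nilotinib and 0.096 for all resistant lines, where it was -0.027 and -0.026, so the added calls are to be read relative to that. Fits of only the groups compared gave 1990, 1 (NMU), 0 and 894. With the dimmest 40% left out, low imatinib had 4 (NIN, ATXN7L3B, FN1, PI4K2B). Trend and robust moderation gave 2 for high imatinib, the same number for nilotinib (FN1 and AFP each time) and 268 for all resistant lines. For nilotinib, every array feature, quantile normalization and removal of the technical axis each gave 0. For all resistant lines, every array feature gave 16, quantile normalization 323 (239 higher and 84 lower, 74.0% higher against 86.4%), a 2-fold minimum 140 and removal of the axis 12 (3 higher, 9 lower), of which 10 were among the 553. Without array 4 of low-imatinib line 1 the counts were 0, 0, 46 and 740. The genes named in brackets and outside the rule were chosen after their values were seen, and apart from settings that leave out samples or genes the cause was not tested.

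Between resistances the reported counts are 0. They were 413 (high against low imatinib), 550 (nilotinib against low imatinib) and 201 (nilotinib against high imatinib) with the random block, 2125, 2615 and 2548 with arrays as independent, and 7, 3 (LOC650226, SGIP1, LRP1) and 1 (DDX60L) with naive arrays as replicates; every array feature gave 2 and 1 features for the comparisons with nilotinib. Leaving out a set leaves its arm with 1 set, assumed to vary like the others. Counts then ranged from 0 to 2 (low imatinib; FN1 and PCED1B without naive K), 0 to 125 (high imatinib; 113 without line 1, 125 without line 2), 0 to 58 (nilotinib; 0 without naive S, 1 without naive K, 6 without line 1, 58 without line 2) and 0 to 1742 (all resistant lines; 0 without naive S or either low-imatinib line, 2 without naive K, 130 and 604 without nilotinib line 1 and 2, 1742 and 923 without high-imatinib line 1 and 2). Between resistances they ranged from 0 to 270 (2 without high-imatinib line 1, 270 without line 2), 0 to 28 (7 without nilotinib line 1, 28 without line 2) and 6 to 35 (25 and 16 without high-imatinib line 1 and 2, 6 and 35 without nilotinib line 1 and 2). Genes shared by the 3 resistances numbered 0, 984 with the random block and 0 to 57 with a set left out.

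Between lines, leaving out 1 array gave 2257 to 2711 (low imatinib), 4443 to 4568 (high imatinib), 3517 to 4154 (nilotinib) and 1126 to 2127 (naive S against K; 1126 without array 2 of S). A 2-fold minimum gave 158, 833, 566 and 41, and removal of the axis gave 2871 for naive S against K. Lists past the threshold numbered 7, 5 and 6 for the resistances and 0, 0 and 0 with an estimated correlation; for high imatinib there were 8 with quantile normalization and 8 with the dimmest genes left out. With a set left out they ranged from 5 to 7, 4 to 5 and 4 to 7. Quantile normalization ended the calls of granulocyte and monocyte genes in low imatinib (camera adjusted p = 0.150), epithelial and fibroblast genes in nilotinib (0.0831), autophagy and lysosome genes in all resistant lines (0.0955) and nilotinib against low imatinib (0.114), Wnt and hedgehog genes in the latter (0.0618), and cell cycle genes (0.0845) and ribosomal proteins (0.264) in nilotinib against high imatinib.

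BCR changed sign without passing in any case: it stood at -0.051 in high imatinib with quantile normalization, between -0.056 (without line 2) and 0.33 with a set left out, and in nilotinib between -0.20 (without line 1) and 0.97 with a set left out. Over all named genes and alternatives, 1134 values kept their direction and side of the threshold, 198 came to pass, 251 no longer passed and 3 reversed. The line numbers do not pair the lines: deviations of same-numbered lines correlated at 0.139, 0.188 and -0.201, and a fit with the replicate number as a block gave 0 genes in each comparison between resistances, as did crossed pairs for nilotinib against high imatinib. The block changed no call. No paired analysis was possible against the naive sets because these share no line number with the resistant lines. Signal over background was not measured here, so genes near the lower end of the scale have no stated limit.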

Other observations

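The genes here were chosen after their values had been seen, and no test beyond the comparisons already described was run on them. LAPTM5, a blood cell gene, stood at 13.20 in high-imatinib line 1 and 11.98 in nilotinib line 2, at 10.46 in nilotinib line 1, at 8.98 and 8.66 in naive S and K, and at 7.09, 6.27 and 6.96 in both low-imatinib lines and high-imatinib line 2. DOCK2, a migration factor of blood cells, followed at 10.20 and 9.64 in the first pair of lines, 7.76 and 7.99 in the naive sets and 6.41, 5.71, 5.76 and 5.83 in nilotinib line 1, the low-imatinib lines and high-imatinib line 2. VAV1, an exchange factor of blood cell signalling, had 9.10 and 8.42, then 7.45 and 7.47, then 6.95, 6.09, 6.03 and 6.11 in the same order. TYROBP, an adaptor of myeloid receptors, had 9.12 and 8.87 in the first pair and between 5.46 and 5.84 in all other sets. None of these 4 genes passed in any comparison with naive cells. The list of granulocyte and monocyte genes had medians against naive of -0.06 and -0.13 in the first pair of lines, -0.16 and -0.25 in high-imatinib line 2 and nilotinib line 1, and -0.23 and -0.19 in the low-imatinib lines.

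AHR stood at 10.34 and 9.57 in naive S and K and at 10.69 in nilotinib line 1, against 6.63 in nilotinib line 2, 6.03 and 5.41 in the low-imatinib lines and 7.40 and 5.56 in the high-imatinib lines. KIT, a receptor that both drugs inhibit, had 8.44 and 8.87 in the naive sets, 9.24 in nilotinib line 1, 7.54 in high-imatinib line 1 and between 5.05 and 5.60 in the others. Among heat shock genes, HSPA1A stood at 12.33 in naive S and 13.18 in naive K and between 9.98 and 11.23 in the resistant lines, and CHORDC1 at 7.42 and 9.0 against 6.29 to 7.12. Other chaperone genes did not pass in all resistant lines against naive: HSPH1 stood at 0.35 ± 0.26, HSPD1 at -0.21 ± 0.13, BAG3 at -0.02 ± 0.14 and HSPB1 at -0.04 ± 0.26.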
